A study of Homo sapiens with 6 samples.

How the data were processed

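SU-DHL-8 cells had been treated for 24 h with 100 nM erianin or with DMSO, and total RNA extracted with TRIzol was sequenced from standard Illumina libraries, per the labels' protocols. The series design names 3 replicate experiments per group but does not say how separate the cultures were, so p-values measure the spread between these libraries, which may be in part technical. Groups and replicate numbers came from the sample labels.

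The authors deposited whole-number read counts per gene and a matching table of TPM, which are length-scaled transcript abundances. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10, featureCounts 2.0.1, StringTie 2.2.1 and the genome build GRCh38 (hg38), without saying which step each served. The annotation release, the handling of strand, read pairs and reads that map to several genes are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical paralogs may therefore be merged or split. Of counts between 1 and 99, 53.1% to 58.1% were even in each library. The deposited TPM values equalled the count divided by a length fixed per gene, times a factor per library, within a relative deviation of 0.000377 over 10205 genes. TPM columns summed to 39.2% of their nominal total in DMSO replicate 1 and 63.6% to 66.7% in the other libraries, so TPM scaled that library differently from the others.

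Each table had 65807 symbols. Repeats of symbols listed more than once (61 entries) were left out, and 65746 stayed, of which 18157 had at least 1 count. No counted entry lacked a gene name. Of the symbols beside the TPM values, 7 differed, having been turned into dates, and were taken from the count table, whose Ensembl identifiers stood in the same order. Coordinates came from GENCODE release 29 (GRCh38), to which 38264 symbols were matched by Ensembl identifier. This release may differ from the one behind the counts. Among protein-coding genes whose symbol differs from that in GENCODE 29, 577 of 634 (91.0%) were listed at 0 in every library, against 3476 of 18521 (18.8%) with the same symbol, so a 0 for a renamed gene was not read as absence of expression.

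The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on counts scaled by TMM, with treatment as the single term, after edgeR's filterByExpr kept 11550 genes. Log2 fold changes are erianin minus DMSO, with a standard error (SE) taken as the size of the fold change over the square root of F. Levels are CPM (counts scaled to library size) with TMM factors, given as mean ± SD (n = 3). Adjusted p-values are Benjamini-Hochberg values from edgeR over all genes tested, called at 0.05. In addition, 31 gene lists fixed before the data were examined were tested by camera (limma 3.58.1) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 28 lists with enough tested members, then by camera with an estimated correlation and by fry. Library-level values were compared by two-sided exact permutation tests of 3 against 3 libraries.

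Named genes followed a rule fixed before the data were examined. It took the 10 genes with the largest rise and the 10 with the largest fall among called genes with an official symbol, at least 10 CPM in the higher group and no overlap between groups. It added 32 genes fixed by name, up to 3 members with the smallest p per list, and the 5 most abundant called genes. It took 4 genes that were not tested for lack of counts, GSDME, NLRP3, IL1B and IL18. Some genes the rule took are not reported here.

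Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling, total counts alone, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, each library left out in turn, and edgeR's glmTreat against a 1.5-fold change. Alternatives chosen after seeing the data were offsets for smooth trends in GC content and gene length per library (mgcv 1.9.3; 11404 tested genes, 98.7%, had both), limma-voom with sample quality weights, the offsets with DMSO replicate 1 left out, and families of gene symbols.

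The fits were tested on simulated counts with the real means and library sizes of this comparison, in 11550 genes of which 200 changed. The edgeR fit recovered 13% of 1.5-fold and 70% of 2-fold changes, with 6.74% of 89 calls false. With a trend planted in 1 library it recovered 1% of 1.5-fold and 15% of 2-fold changes, and with the offsets 15% and 74%. Camera called a planted list and 1 of 30 random lists. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The total counts of 30956443 to 35588728 make 3 counts equal 0.084 to 0.097 CPM. If read pairs were counted as separate reads, the counting error is larger than this.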

Results

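RNA sequencing measured gene expression in SU-DHL-8, an established human diffuse large B-cell lymphoma line, after 24 h with 100 nM erianin or with DMSO. Erianin is a bibenzyl compound from Dendrobium orchids that is described as a tubulin ligand. Each group had 3 libraries, numbered as replicate experiments. Total counts were 30956443, 34215321 and 35588728 in DMSO replicates 1, 2 and 3. They were 35307027, 32844464 and 34130896 in erianin replicates 1, 2 and 3. A count of 3, used here as the floor, equals 0.084 to 0.097 counts scaled to a common depth (CPM) and covers counting error only. At least 1 count was found for 14399 ± 248 genes with DMSO and 15015 ± 25.0 genes with erianin (mean ± SD, n = 3). This gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.

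DMSO replicate 1 stood apart from the other libraries. Ribosomal protein genes took 8.54% of its counts, against 12.51% and 12.42% in DMSO replicates 2 and 3. Their share in the erianin libraries was 11.8% ± 0.306 (SD, n = 3). The biological coefficient of variation was 0.292 and 0.295 between DMSO replicate 1 and the other DMSO libraries. It was 0.0380 between DMSO replicates 2 and 3, and 0.0336 to 0.0815 between erianin libraries. All 6 libraries entered the fit, and counts without DMSO replicate 1 stand beside those with it.

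**Figure D1:**
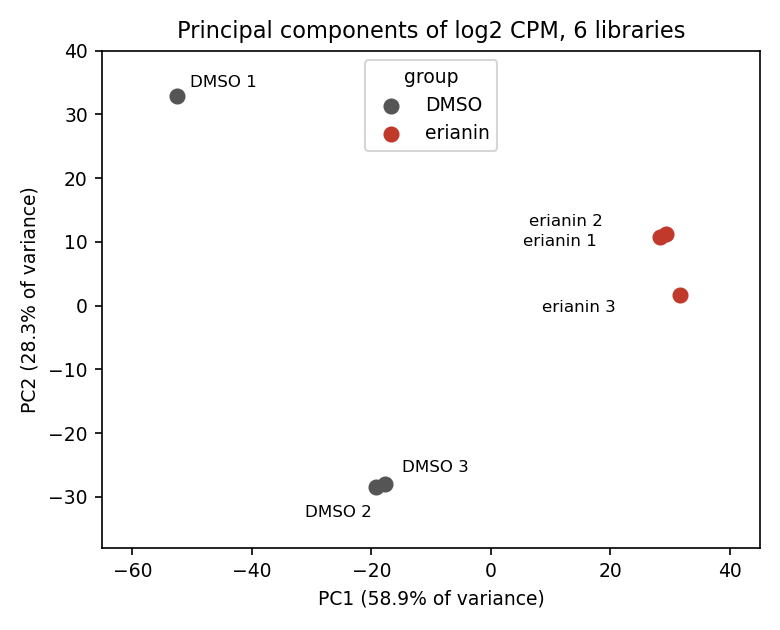
Principal components of log2 CPM over the 11550 genes tested, with 1 point per library, DMSO in grey and erianin in red. The first component (58.9% of the variance) places the 3 erianin libraries at 28.4 to 31.6 and the DMSO libraries at -52.5, -19.2 and -17.6, and the second (28.3%) places DMSO replicate 1 at 32.9 and the other DMSO libraries at -28.5 and -28.1.

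The comparison of erianin with DMSO asked which transcripts the compound changes. The series title names pyroptosis through GSDMD, doxorubicin and the PI3K/AKT pathway, and genes of each were among the lists fixed before the data were examined. FOSB, a subunit of the AP-1 transcription factor, rose most among named genes of at least 10 CPM (log2 fold change 3.15 ± 0.16, adjusted p = 0.00022). PFKFB4, a regulator of glycolysis, rose as well (2.67 ± 0.14, adjusted p = 0.00030). MKNK2, a kinase that phosphorylates the translation factor eIF4E, rose from 80.7 ± 8.53 to 495 ± 33.0 CPM. HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose from 19.96 ± 1.57 to 108 ± 4.35 CPM. RGS16, a regulator of G protein signalling, fell from 45.5 ± 7.11 to 7.24 ± 0.808 CPM (-2.65 ± 0.16, adjusted p = 0.00030). FADS2, a fatty acid desaturase gene, fell from 39.2 ± 1.01 to 6.71 ± 0.657 CPM. TMCC2 fell from 80.9 ± 9.21 to 15.5 ± 1.59 CPM. Of the 11550 genes tested, 1368 rose and 1423 fell, and 688 of them changed at least 2-fold, 483 upwards and 205 downwards. Without DMSO replicate 1, 3278 rose and 3227 fell, and 2784 of the 2791 genes called with all 6 libraries were called in the same direction.

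MIR210HG (2.83 ± 0.22), HMGCS1, HSPA1B, CDKN1A and TXNIP were also among the 10 genes with the largest rise. The largest falls also included TP63, a p53 family member (-2.25 ± 0.36), EPHX1 (-2.20 ± 0.13), TTYH2 (-1.93 ± 0.12) and LTB, which encodes lymphotoxin beta (-1.92 ± 0.23). PLXNA1 (-1.90 ± 0.17), RASSF6 (-1.75 ± 0.21) and CCRL2 (-1.74 ± 0.16) completed these 10. For TP63 the DMSO libraries spread widely (16.6 ± 9.07 CPM with DMSO and 3.48 ± 0.187 CPM with erianin), and without DMSO replicate 1 its log2 fold change was -1.69 ± 0.14, adjusted p = 2.0e-10. The 5 most abundant genes called moved by less. HSP90AB1 rose from 5212 ± 329.9 to 7436 ± 165 CPM and ACTB rose from 3369 ± 247 to 4640.3 ± 229 CPM. CCND3, which encodes a D-type cyclin, fell from 2855 ± 387 to 1731 ± 88.7 CPM. The immunoglobulin genes IGLV1-44 and IGHG3 fell by 0.43 and 0.67 on the log2 scale. HSP90AB1 and IGLV1-44 lost their calls without any 1 library other than DMSO replicate 1 (adjusted p up to 0.076 and 0.13). ACTB lost its call without DMSO replicate 2 or any erianin library (up to 0.089), CCND3 without erianin replicate 1 or 2 (up to 0.064), and IGHG3 without any erianin library (up to 0.17). The calls of IGLV1-44 and IGHG3 also ended with upper-quartile scaling (adjusted p = 0.052 and 0.062) and with total counts alone (adjusted p = 0.055 and 0.082). The 1 CPM filter (adjusted p = 0.051) and GC content and length offsets (adjusted p = 0.058) ended that of IGHG3 as well. The log2 fold change of IGLV1-44 was -0.85 with the offsets, and that of IGHG3 -0.41 without DMSO replicate 1. Immunoglobulin genes have near-identical copies between which reads can be split, so their levels are uncertain.

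Named chaperone genes of the cytosol and of the endoplasmic reticulum rose. HSPA1B, an inducible HSP70 gene (chromosome 6, 31827735 to 31830255, plus strand), rose from 6.30 ± 1.53 to 34.7 ± 2.09 CPM (2.46 ± 0.19, adjusted p = 0.00092). Its near-identical paralog HSPA1A can share its reads. The co-chaperone gene DNAJA1 rose from 149.9 ± 22.4 to 425 ± 27.7 CPM, and HSPH1 rose from 195 ± 24.7 to 450.4 ± 8.51 CPM. Of 18 heat shock genes tested, 10 rose, 0 fell and 8 were not called, with 17 higher and 0 lower without DMSO replicate 1. The heat shock list held 13 higher and 0 lower genes adjusted over the list alone. Heat shock genes together had a median log2 fold change of 0.83 (adjusted p = 5.5e-10 by camera and adjusted p = 0.085 with an estimated correlation). HSPA5, which encodes the lumenal chaperone BiP (chromosome 9, 125234853 to 125241330, minus strand), rose from 89.7 ± 0.752 to 319 ± 7.46 CPM (1.83 ± 0.09, adjusted p = 0.00022). HSP90B1 rose from 221 ± 34.8 to 458 ± 22.5 CPM. CALR, which encodes calreticulin, rose from 446 ± 22.9 to 831 ± 34.8 CPM. Of 19 endoplasmic reticulum chaperone genes tested, 8 rose, 2 fell and 9 were not called, with 14 higher and 2 lower without DMSO replicate 1. XBP1, also on this list, fell (-0.55, adjusted p = 0.0081) and was not called without erianin replicate 1 or 2. The endoplasmic reticulum chaperone list held 10 higher and 2 lower genes adjusted over the list alone. Endoplasmic reticulum chaperone genes together had a median log2 fold change of 0.40 (adjusted p = 0.00082 by camera and adjusted p = 0.085 with an estimated correlation).

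Most immediate early genes rose too. FOSB (chromosome 19, 45467995 to 45475179, plus strand) rose from 3.16 ± 0.599 to 27.995 ± 0.352 CPM. FOS rose from 1.69 ± 0.423 to 9.33 ± 0.834 CPM (2.47 ± 0.21, adjusted p = 0.0011). JUNB rose from 43.4 ± 1.87 to 97.2 ± 7.74 CPM (1.16 ± 0.11, adjusted p = 0.0013). The call of JUNB ended with offsets for GC content and gene length (log2 fold change 0.70, adjusted p = 0.067). ATF3, a stress-induced gene of the same list, had 16.1 ± 3.12 CPM with DMSO and 17.9 ± 1.17 CPM with erianin (adjusted p = 0.54). Of 25 AP-1 and immediate early genes tested, 16 rose, 1 fell and 8 were not called, with 19 of 26 higher and 2 lower without DMSO replicate 1. The AP-1 and immediate early list held 19 higher and 2 lower genes adjusted over the list alone. AP-1 and immediate early genes together had a median log2 fold change of 1.16 (adjusted p = 3.4e-11 by camera and adjusted p = 0.071 with an estimated correlation).

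Named genes of sterol and glucose metabolism rose. HMGCS1, the cytosolic HMG-CoA synthase (chromosome 5, 43289395 to 43313512, minus strand), rose from 14.1 ± 1.94 to 80.6 ± 7.39 CPM (2.52 ± 0.14, adjusted p = 0.00030). Of 23 cholesterol synthesis genes tested, 14 rose, 0 fell and 9 were not called, with 17 higher and 0 lower without DMSO replicate 1. The cholesterol synthesis list held 14 higher and 0 lower genes adjusted over the list alone. Cholesterol synthesis genes together had a median log2 fold change of 0.92 (adjusted p = 2.6e-17 by camera and adjusted p = 0.085 with an estimated correlation). PFKFB4 rose from 4.81 ± 0.616 to 30.7 ± 2.41 CPM. PFKFB3, which makes the same glycolytic activator, rose from 18.4 ± 3.23 to 45.7 ± 2.45 CPM. LDHA, a lactate dehydrogenase gene, rose from 926 ± 65.1 to 1767 ± 132 CPM. MIR210HG, the host transcript of a hypoxia-induced microRNA, was outside this list and rose from 1.51 ± 0.397 to 10.7 ± 1.31 CPM. Of 28 glycolysis and hypoxia genes tested, 10 rose, 0 fell and 18 were not called, with 16 higher and 1 lower without DMSO replicate 1. The glycolysis and hypoxia list held 11 higher and 0 lower genes adjusted over the list alone. Glycolysis and hypoxia genes together had a median log2 fold change of 0.40 (adjusted p = 1.1e-05 by camera and adjusted p = 0.11 with an estimated correlation).

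Replication genes fell, while genes of mitosis went both ways. CDT1, a replication licensing factor, fell from 565 ± 61.2 to 249 ± 20.4 CPM (-1.18 ± 0.12, adjusted p = 0.0019). CDC45, part of the replicative helicase, fell from 265 ± 10.8 to 132 ± 6.81 CPM. CCNE1, which encodes cyclin E1, fell from 68.6 ± 3.15 to 37.2 ± 1.89 CPM. Of 41 DNA replication and G1/S genes tested, 0 rose, 28 fell and 13 were not called, with 1 higher and 33 lower without DMSO replicate 1. The DNA replication and G1/S list held 0 higher and 29 lower genes adjusted over the list alone. DNA replication and G1/S genes together had a median log2 fold change of -0.55 (adjusted p = 4.0e-12 by camera and adjusted p = 0.028 with an estimated correlation). CCNB1, which encodes cyclin B1, rose from 114 ± 19.9 to 345 ± 14.7 CPM (1.598 ± 0.15, adjusted p = 0.0013). The CDK1-activating phosphatase genes CDC25B (from 1419 ± 29.3 to 586 ± 21.8 CPM) and CDC25C (from 22.7 ± 2.03 to 9.56 ± 0.994 CPM) fell. PLK1, a mitotic kinase, had 251 ± 33.5 CPM with DMSO and 279 ± 16.2 CPM with erianin (adjusted p = 0.42), and without DMSO replicate 1 it rose (0.28 ± 0.06, adjusted p = 0.00052). Of 40 mitosis and spindle genes tested, 5 rose, 13 fell and 22 were not called, with 11 higher and 17 lower without DMSO replicate 1. The mitosis and spindle list held 6 higher and 15 lower genes adjusted over the list alone. Mitosis and spindle genes together had a median log2 fold change of -0.27 (adjusted p = 0.036 by camera and adjusted p = 0.57 with an estimated correlation). This list was not called without DMSO replicate 1 (adjusted p = 0.26), without erianin replicate 3 (adjusted p = 0.067) or with total counts alone (adjusted p = 0.057). Nor was it called with the 1 CPM filter (adjusted p = 0.066), on the log2(TPM + 1) scale (adjusted p = 0.051) or by fry (adjusted p = 0.11). Its median turned to 0.018 on the log2(TPM + 0.1) scale.

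Tubulin genes went both ways. TUBB, the most abundant of the named tubulin genes with DMSO, fell from 1356 ± 107 to 763 ± 22.1 CPM (-0.83 ± 0.10, adjusted p = 0.0033). TUBA1A, an alpha-tubulin gene, rose from 167 ± 21.9 to 368 ± 21.1 CPM (1.13 ± 0.12, adjusted p = 0.0022). The low-level TUBB1 rose from 1.26 ± 0.120 to 2.81 ± 0.693 CPM (not called without erianin replicate 1, adjusted p = 0.058). TUBA1B had 1176 ± 265 CPM with DMSO and 1121 ± 109 CPM with erianin (adjusted p = 0.81), and without DMSO replicate 1 it fell (-0.23 ± 0.07, adjusted p = 0.0054). TUBB4B had 425 ± 93.3 CPM with DMSO and 625 ± 35.8 CPM with erianin (adjusted p = 0.052), and without DMSO replicate 1 it rose (0.40 ± 0.06, adjusted p = 6.6e-06). TUBB4B was also called higher with the offsets, upper-quartile scaling, total counts, DESeq2, limma-voom and other filters (adjusted p = 0.0068 to 0.048). Of 15 tubulin genes tested, 3 rose, 3 fell and 9 were not called, with 6 of 16 higher and 4 lower without DMSO replicate 1. The tubulin list held 4 higher and 3 lower genes adjusted over the list alone. Tubulin genes as a list were not called (adjusted p = 0.56 by camera). Tubulin paralogs are similar in sequence, and TUBA1A shares 490 of 3421 exonic bases with TUBA1C on the opposite strand, so reads of these genes can be split or merged.

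CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339, plus strand), rose from 2.99 ± 0.891 to 15.6 ± 1.64 CPM (2.38 ± 0.23, adjusted p = 0.0016). PLK3 rose from 3.08 ± 0.440 to 7.49 ± 0.156 CPM. SESN1 rose from 9.20 ± 0.660 to 15.7 ± 0.666 CPM. Of 22 p53 target genes tested, 6 rose, 2 fell and 14 were not called, with 10 higher and 7 lower without DMSO replicate 1. The p53 target list held 6 higher and 2 lower genes adjusted over the list alone. P53 target genes as a list were not called (adjusted p = 0.092 by camera).

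GSDMD, the pore-forming gasdermin cleaved in pyroptosis (ENSG00000104518, chromosome 8, 143553207 to 143563062, plus strand), was not called. It had 55.1 ± 22.02 CPM with DMSO and 43.96 ± 2.53 CPM with erianin (n = 3 each; log2 fold change -0.33 ± 0.29, adjusted p = 0.46). Its level was 29.7 CPM in DMSO replicate 1 and 68.1 and 67.5 CPM in the other DMSO libraries, and without DMSO replicate 1 it fell (-0.61 ± 0.07, adjusted p = 1.4e-07). GSDMD was not called with GC content and length offsets (-0.35, adjusted p = 0.17) or with the replicate block (adjusted p = 0.54). Nor was it called without any other single library (adjusted p up to 0.77). CASP1, the inflammasome caspase, had 13.4 ± 1.51 CPM with DMSO and 12.8 ± 0.641 CPM with erianin (adjusted p = 0.74). CASP4, the noncanonical inflammasome caspase, had 32.6 ± 14.2 CPM with DMSO and 28.9 ± 1.45 CPM with erianin (adjusted p = 0.69), and without DMSO replicate 1 it rose (0.25 ± 0.09, adjusted p = 0.024). NLRP3, IL1B and GSDME were listed at 0 in all 6 libraries. None of these is among the genes whose symbol differs from that in GENCODE 29, so renaming against that release does not account for their 0. The annotation used for counting is not known, so their 0 was not read as absence of expression. IL18 had 2 counts, both in DMSO replicate 1. TXNIP, an arrestin-like protein that binds thioredoxin, rose from 43.7 ± 3.14 to 218 ± 9.91 CPM (2.32 ± 0.11, adjusted p = 0.00021). The nucleic acid sensor ZBP1 rose from 0.383 ± 0.0759 to 1.21 ± 0.249 CPM (not called without erianin replicate 1, adjusted p = 0.052). Of 15 pyroptosis and inflammasome genes tested, 2 rose, 0 fell and 13 were not called, with 4 higher and 3 lower without DMSO replicate 1. The pyroptosis and inflammasome list held 2 higher and 0 lower genes adjusted over the list alone. Pyroptosis and inflammasome genes as a list were not called (adjusted p = 0.068 by camera, with a median of -0.05 and a mean of 0.37 against a test direction of higher). The pyroptosis and inflammasome median ran from -0.06 to 0.22 over the other settings, with 0.17 without DMSO replicate 1.

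Components of the PI3K/AKT/mTOR pathway went both ways. RPTOR, the scaffold of mTORC1, fell from 110.5 ± 11.8 to 53.5 ± 1.82 CPM (-1.05 ± 0.11, adjusted p = 0.0023). MLST8, another mTOR complex subunit, fell from 159.6 ± 7.68 to 89.7 ± 4.73 CPM. PHLPP2, an AKT phosphatase gene, rose from 9.99 ± 0.784 to 17.7 ± 1.46 CPM. AKT2 fell from 317 ± 20.7 to 241 ± 16.1 CPM (-0.39 ± 0.10, adjusted p = 0.032). It was not called without any 1 library other than DMSO replicate 1, adjusted p up to 0.16. Its call also ended with upper-quartile scaling (adjusted p = 0.076), with total counts alone (adjusted p = 0.073) and without a filter. AKT1 had 295 ± 63.4 CPM with DMSO and 259.6 ± 22.9 CPM with erianin (adjusted p = 0.48). PIK3CD had 273 ± 51.1 CPM with DMSO and 236 ± 6.58 CPM with erianin (adjusted p = 0.34), and PIK3CA had 44.7 ± 7.79 CPM with DMSO and 37.3 ± 2.44 CPM with erianin (adjusted p = 0.23). PIK3R1 had 41.7 ± 9.71 CPM with DMSO and 55.5 ± 4.39 CPM with erianin (adjusted p = 0.12). Without DMSO replicate 1, AKT1 (-0.34 ± 0.07, adjusted p = 0.00010) and PIK3CD (-0.35 ± 0.06, adjusted p = 1.7e-05) fell and PIK3R1 rose (0.63 ± 0.08, adjusted p = 3.8e-07). With GC content and length offsets PIK3CA was called lower (-0.29, adjusted p = 0.020) and PIK3R1 higher (0.51, adjusted p = 0.0031), and PIK3R1 was called higher on the log2(TPM + 1) scale too (adjusted p = 0.021). AKT1 and PIK3CD were not called with the offsets (adjusted p = 0.30 and 0.18), nor was PIK3CA without DMSO replicate 1 (-0.096 ± 0.08, adjusted p = 0.32). Of 31 PI3K/AKT/mTOR genes tested, 4 rose, 8 fell and 19 were not called, with 8 of 32 higher and 11 lower without DMSO replicate 1. The PI3K/AKT/mTOR list held 4 higher and 8 lower genes adjusted over the list alone. PI3K/AKT/mTOR genes as a list were not called (adjusted p = 0.37 by camera). FBXO32, induced by the FOXO factors that AKT inhibits, fell from 4.28 ± 0.0964 to 2.02 ± 0.0799 CPM, while TXNIP and SESN1 of the same list rose. Of 19 FOXO target genes tested, 3 rose, 4 fell and 12 were not called, with 8 higher and 7 lower without DMSO replicate 1. The FOXO target list held 4 higher and 5 lower genes adjusted over the list alone. FOXO target genes as a list were not called (adjusted p = 0.52 by camera). These values are of mRNA and hold no measure of phosphorylation or cleavage.

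**Figure D2:**
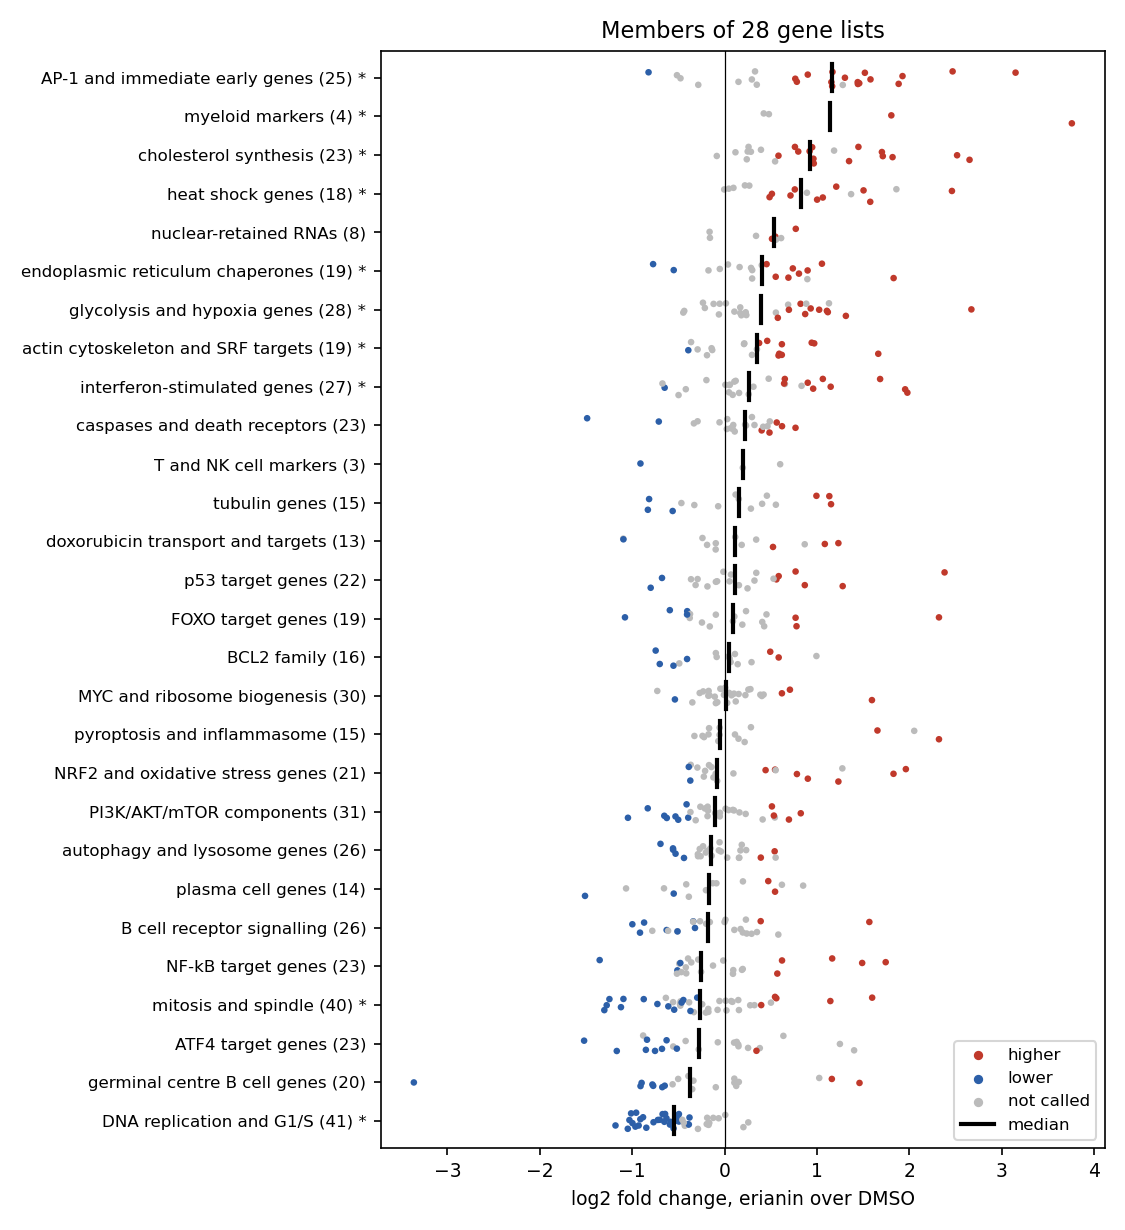
Log2 fold change of each tested member of 28 gene lists, with 1 point per gene, red for genes that rose, blue for those that fell and grey for those not called. The black bar is the median, the number tested is in brackets and a star marks a camera adjusted p under 0.05, with the AP-1 and immediate early median at 1.16 and the DNA replication median at -0.55.

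Genes of cell death changed in both directions. The anti-apoptotic BCL2L1 fell from 299 ± 7.30 to 204 ± 10.98 CPM (-0.55 ± 0.09, adjusted p = 0.0076; not called without erianin replicate 1 or 2, adjusted p up to 0.065). BCL2 fell from 13.97 ± 0.352 to 8.59 ± 1.07 CPM (not called without erianin replicate 1, adjusted p = 0.066). MCL1, also anti-apoptotic, rose from 280.5 ± 4.96 to 395 ± 14.1 CPM (not called without erianin replicate 1 or 2, adjusted p up to 0.067). The pro-apoptotic HRK fell from 12.6 ± 0.438 to 7.51 ± 0.816 CPM (not called without erianin replicate 1, adjusted p = 0.059). BCL2A1 had 1.11 ± 0.125 CPM with DMSO and 0.790 ± 0.3002 CPM with erianin (adjusted p = 0.31). Of 16 BCL2 family genes tested, 2 rose, 4 fell and 10 were not called, with 2 higher and 6 lower without DMSO replicate 1. The BCL2 family list held 2 higher and 4 lower genes adjusted over the list alone. BCL2 family genes as a list were not called (adjusted p = 0.74 by camera, with a median of 0.05 and a mean of -0.02 against a test direction of lower). The BCL2 family median ran from -0.28 to 0.37 over the other settings, with -0.24 without DMSO replicate 1. TNFRSF1A, a TNF receptor gene, fell from 6.96 ± 0.591 to 2.48 ± 0.688 CPM (-1.49 ± 0.22, adjusted p = 0.0054). CASP8 rose from 24.9 ± 3.87 to 42.5 ± 2.24 CPM (not called without erianin replicate 1 or 2, adjusted p up to 0.054). Its regulator CFLAR rose from 10.5 ± 0.585 to 16.2 ± 0.206 CPM (not called without erianin replicate 1 or 2, adjusted p up to 0.058). Of 23 caspase and death receptor genes tested, 5 rose, 2 fell and 16 were not called, with 11 higher and 3 lower without DMSO replicate 1. The caspase and death receptor list held 7 higher and 2 lower genes adjusted over the list alone. Caspase and death receptor genes as a list were not called (adjusted p = 0.28 by camera).

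TOP2A, the topoisomerase that doxorubicin poisons, fell from 557 ± 83.3 to 261 ± 15.4 CPM (-1.09 ± 0.13, adjusted p = 0.0028). The efflux pump gene ABCC2 rose from 2.37 ± 0.417 to 5.04 ± 0.146 CPM. NQO1, a quinone reductase, rose from 10.9 ± 3.66 to 25.7 ± 0.574 CPM (not called without erianin replicate 1, 2 or 3, adjusted p up to 0.059). ABCB1, which encodes the efflux pump P-glycoprotein, had 1.35 ± 0.185 CPM with DMSO and 0.625 ± 0.286 CPM with erianin (adjusted p = 0.053). Without DMSO replicate 1 (log2 fold change -0.99 ± 0.35, adjusted p = 0.019) or erianin replicate 1 ABCB1 was called lower. It was also called lower with the offsets, DESeq2, limma-voom and other filters (adjusted p = 0.017 to 0.049). Of 13 doxorubicin transport and target genes tested, 3 rose, 1 fell and 9 were not called, with 6 higher and 3 lower without DMSO replicate 1. The doxorubicin transport and target list held 3 higher and 2 lower genes adjusted over the list alone. Doxorubicin transport and target genes as a list were not called (adjusted p = 0.65 by camera).

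Genes of B-cell identity and signalling changed in both directions. P2RY8 rose from 15.9 ± 0.273 to 35.7 ± 1.53 CPM, and the transcription factor SPIB rose from 33.4 ± 8.05 to 92.0 ± 1.49 CPM. BCL6 had 9.53 ± 4.01 CPM with DMSO and 10.2 ± 0.486 CPM with erianin (adjusted p = 0.81), and without DMSO replicate 1 it rose (0.52 ± 0.12, adjusted p = 0.00084). Of 20 germinal centre genes tested, 2 rose, 7 fell and 11 were not called, with 5 higher and 8 lower without DMSO replicate 1. The germinal centre list held 3 higher and 8 lower genes adjusted over the list alone. Germinal centre genes as a list were not called (adjusted p = 0.068 by camera). The germinal centre list was called lower without DMSO replicate 2 (adjusted p = 0.019) or DMSO replicate 3 (adjusted p = 0.048), calls lost with an estimated correlation (adjusted p = 0.53 and 0.60). PTPN6, which encodes the phosphatase SHP-1, rose from 19.8 ± 1.32 to 58.7 ± 4.62 CPM (1.57 ± 0.11, adjusted p = 0.00072). PAX5, the B-lineage transcription factor, fell from 836 ± 84.8 to 419 ± 12.9 CPM (-0.998 ± 0.11, adjusted p = 0.0023). The kinase gene BLK fell from 65.2 ± 3.87 to 42.2 ± 3.41 CPM (not called without erianin replicate 1 or 2, adjusted p up to 0.064). Of 26 B-cell receptor signalling genes tested, 2 rose, 7 fell and 17 were not called, with 6 higher and 10 lower without DMSO replicate 1. The B-cell receptor signalling list held 2 higher and 7 lower genes adjusted over the list alone. B-cell receptor signalling genes as a list were not called (adjusted p = 0.44 by camera). CD27 fell from 8.29 ± 1.34 to 2.91 ± 0.479 CPM, with 522 of its 1410 exonic bases shared with an antisense gene. XBP1 fell from 125 ± 4.32 to 85.3 ± 3.13 CPM (not called without erianin replicate 1 or 2, adjusted p up to 0.066). MZB1 rose from 206 ± 9.18 to 301 ± 16.6 CPM (not called without erianin replicate 2, adjusted p = 0.054). Of 14 plasma cell genes tested, 2 rose, 2 fell and 10 were not called, with 4 higher and 5 lower without DMSO replicate 1. The plasma cell list held 2 higher and 3 lower genes adjusted over the list alone. Plasma cell genes as a list were not called (adjusted p = 0.49 by camera).

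**Figure D3:**
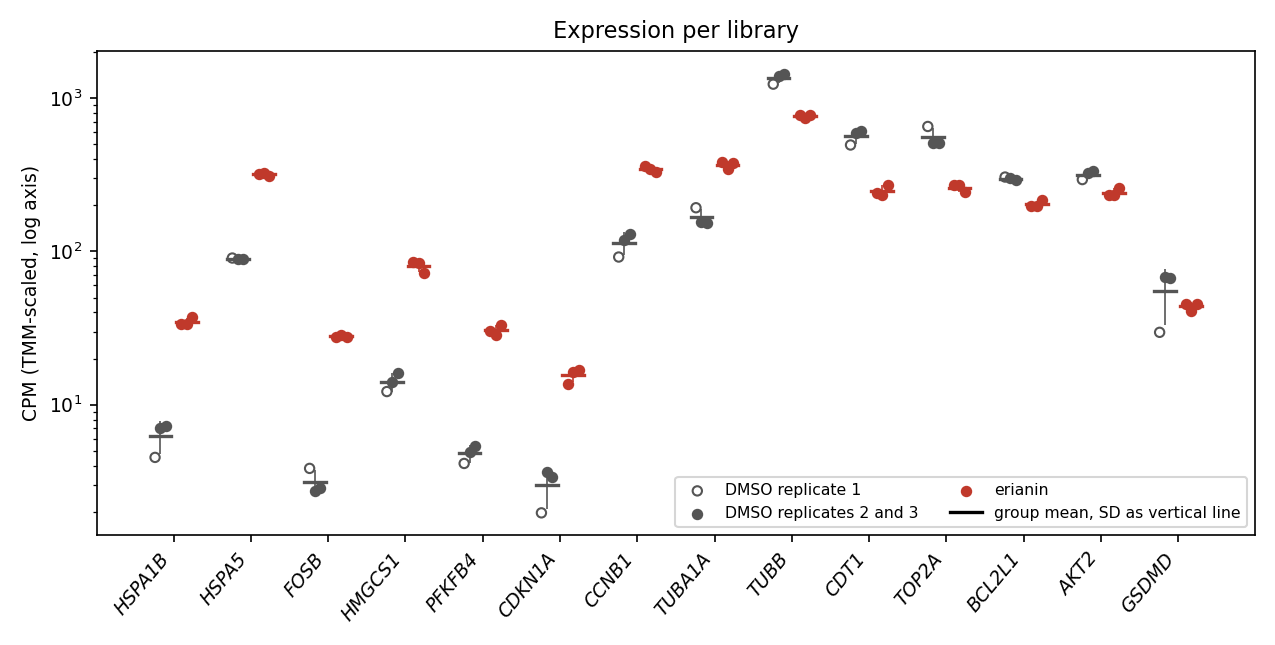
CPM of 14 genes in each of the 6 libraries on a log axis, with DMSO in grey (open circle for DMSO replicate 1) and erianin in red, horizontal bars for group means and vertical lines for the SD (n = 3). HSPA5, FOSB, HMGCS1 and CCNB1 lie higher in all 3 erianin libraries, CDT1, TOP2A and TUBB lie lower, and GSDMD with erianin (43.96 ± 2.53 CPM) lies between DMSO replicate 1 and the other DMSO libraries.

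Named interferon-stimulated genes rose from low levels. IFIT5 rose from 6.71 ± 0.711 to 14.02 ± 0.469 CPM, and IFI27 rose from 0.535 ± 0.110 to 2.12 ± 0.389 CPM. IFIT3 rose from 1.48 ± 0.162 to 3.28 ± 0.476 CPM (not called without erianin replicate 2, adjusted p = 0.051). Of 27 interferon-stimulated genes tested, 9 rose, 1 fell and 17 were not called, with 13 higher and 3 lower without DMSO replicate 1. The interferon-stimulated list held 11 higher and 2 lower genes adjusted over the list alone. Interferon-stimulated genes together had a median log2 fold change of 0.26 (adjusted p = 0.011 by camera and adjusted p = 0.12 with an estimated correlation). That call was lost without DMSO replicate 1 (adjusted p = 0.091 by camera) and on the log2(TPM + 1) scale (adjusted p = 0.058). TNF rose from 1.81 ± 0.518 to 6.09 ± 0.213 CPM (1.74 ± 0.23, adjusted p = 0.0035). RELB, an NF-kB subunit gene, fell from 149 ± 46.8 to 58.2 ± 4.203 CPM (-1.35 ± 0.24, adjusted p = 0.0086; not called without erianin replicate 1 or 2, adjusted p up to 0.054). Of 23 NF-kB target genes tested, 5 rose, 3 fell and 15 were not called, with 7 higher and 8 lower without DMSO replicate 1. The NF-kB target list held 5 higher and 4 lower genes adjusted over the list alone. NF-kB target genes as a list were not called (adjusted p = 0.98 by camera, with a median of -0.25 and a mean of 0.0037 against a test direction of higher). The NF-kB target median ran from -0.27 to 0.02 over the other settings, with -0.11 without DMSO replicate 1. ZYX, which encodes zyxin, rose from 7.78 ± 1.07 to 24.6 ± 0.834 CPM (1.66 ± 0.14, adjusted p = 0.00099). FLNA, which encodes filamin A, rose from 616 ± 159.6 to 1208 ± 93.9 CPM (not called without erianin replicate 1, 2 or 3, adjusted p up to 0.068). SRF rose from 261 ± 5.34 to 391.9 ± 28.3 CPM, a call that ended with GC content and length offsets (log2 fold change 0.35, adjusted p = 0.11). Of 19 actin and SRF genes tested, 9 rose, 1 fell and 9 were not called, with 11 higher and 4 lower without DMSO replicate 1. CCN1 and CCN2, whose symbols differ from those in GENCODE 29, were listed at 0 and not tested. The actin and SRF list held 9 higher and 2 lower genes adjusted over the list alone. Actin and SRF genes together had a median log2 fold change of 0.35 (adjusted p = 0.016 by camera and adjusted p = 0.20 with an estimated correlation). Without erianin replicate 3 the list was not called (adjusted p = 0.063 by camera), nor on the log2(TPM + 1) or log2(TPM + 0.1) scale (adjusted p = 0.064 and 0.077).

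SLC7A1, a cationic amino acid transporter, fell from 758 ± 59.2 to 424 ± 20.1 CPM. MTHFD2, a mitochondrial folate enzyme, fell from 316 ± 3.59 to 187 ± 11.8 CPM. CTH, which makes cysteine, fell from 29.7 ± 4.95 to 13.2 ± 1.52 CPM. DDIT3, which encodes CHOP, had 44.3 ± 7.18 CPM with DMSO and 52.9 ± 5.98 CPM with erianin (adjusted p = 0.27). Of 23 ATF4 target genes tested, 1 rose, 8 fell and 14 were not called, with 4 higher and 12 lower without DMSO replicate 1. AARS1, GARS1 and WARS1, whose symbols differ from those in GENCODE 29, were listed at 0 and not tested. The ATF4 target list held 2 higher and 10 lower genes adjusted over the list alone. ATF4 target genes as a list were not called (adjusted p = 0.065 by camera). On the log2(TPM + 1) and log2(TPM + 0.1) scales camera called this list, although its median turned slightly positive there. Without DMSO replicate 1 the ATF4 list was called lower (adjusted p = 0.00027 by camera; adjusted p = 0.16 with an estimated correlation). TXNRD1 rose from 161 ± 9.46 to 277 ± 11.8 CPM. HMOX1 rose from 0.289 ± 0.0908 to 1.14 ± 0.268 CPM, near the floor with DMSO. Of 21 NRF2 and oxidative stress genes tested, 7 rose, 2 fell and 12 were not called, with 10 higher and 7 lower without DMSO replicate 1. The NRF2 and oxidative stress list held 9 higher and 4 lower genes adjusted over the list alone. NRF2 and oxidative stress genes as a list were not called (adjusted p = 0.16 by camera, with a median of -0.08 and a mean of 0.34 against a test direction of higher). The NRF2 and oxidative stress median ran from -0.09 to 0.23 over the other settings, with 0.13 without DMSO replicate 1. ODC1, the first enzyme of polyamine synthesis, rose from 492 ± 12.8 to 803 ± 35.6 CPM. MYC itself had 710.0 ± 259 CPM with DMSO and 429 ± 18.3 CPM with erianin (adjusted p = 0.060). It was called lower without DMSO replicate 1 (-0.38 ± 0.06, adjusted p = 1.1e-05), without DMSO replicate 3, with DESeq2 (adjusted p = 0.017) and without a filter (adjusted p = 0.032). Of 30 MYC and ribosome biogenesis genes tested, 3 rose, 1 fell and 26 were not called, with 11 higher and 7 lower without DMSO replicate 1. The MYC and ribosome biogenesis list held 3 higher and 0 lower genes adjusted over the list alone. MYC and ribosome biogenesis genes as a list were not called (adjusted p = 0.53 by camera). The proton pump gene ATP6V0D1 fell from 136 ± 13.5 to 92.5 ± 1.25 CPM (not called without erianin replicate 1, 2 or 3, adjusted p up to 0.074). Of 26 autophagy and lysosome genes tested, 2 rose, 5 fell and 19 were not called, with 7 higher and 12 lower without DMSO replicate 1. The autophagy and lysosome list held 3 higher and 5 lower genes adjusted over the list alone. Autophagy and lysosome genes as a list were not called (adjusted p = 0.37 by camera).

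Markers of other cell types were under 10 CPM in every library. CD14 rose from 0.109 ± 0.139 to 1.57 ± 0.0245 CPM, and CSF1R rose from 0.123 ± 0.0282 to 0.441 ± 0.117 CPM (not called without DMSO replicate 2 or 3 or erianin replicate 1 or 2, adjusted p up to 0.091). Of 4 myeloid marker genes tested, 2 rose, 0 fell and 2 were not called, with 2 higher and 0 lower without DMSO replicate 1. The myeloid marker list held 2 higher and 0 lower genes adjusted over the list alone. Myeloid marker genes together had a median log2 fold change of 1.14 (adjusted p = 0.010 by camera and adjusted p = 0.20 with an estimated correlation). With DMSO, CD14 and CSF1R lay near the floor, so they could pass the filter only through their levels with erianin. A rise among the tested myeloid markers was thus favoured in advance, and the camera result is no evidence of a myeloid change. The myeloid call was lost without DMSO replicate 1 (adjusted p = 0.26) and without erianin replicate 3 (adjusted p = 0.060). It also ended with limma-voom (adjusted p = 0.057), without a filter (adjusted p = 0.073) and on the log2(TPM + 1) and log2(TPM + 0.1) scales (adjusted p = 0.20 and 0.090). TRAC fell from 3.38 ± 0.389 to 1.80 ± 0.440 CPM (not called without DMSO replicate 2 or erianin replicate 1, 2 or 3, adjusted p up to 0.10). Of 3 T and NK cell marker genes tested, 0 rose, 1 fell and 2 were not called, with 0 higher and 1 lower without DMSO replicate 1. The T and NK cell marker list held 0 higher and 1 lower genes adjusted over the list alone. T and NK cell marker genes as a list were not called (adjusted p = 0.89 by camera, with a median of 0.20 and a mean of -0.04 against a test direction of lower). The T and NK cell marker median ran from -0.27 to 0.63 over the other settings, with -0.16 without DMSO replicate 1. CLDN4, the single epithelial marker tested, fell from 1.91 ± 0.133 to 0.405 ± 0.106 CPM. NEAT1, an RNA held in the nucleus, rose from 57.7 ± 3.80 to 84.5 ± 1.66 CPM (not called without erianin replicate 1 or 2, adjusted p up to 0.061). Of 8 genes tested on the list named nuclear-retained RNAs, 3 rose (NEAT1, NORAD and KCNQ1OT1), 0 fell and 5 were not called. In the fit without DMSO replicate 1, 5 were higher and 0 lower. Where the members of this list, NORAD among them, lie in the cell was not tested. The nuclear-retained RNA list held 5 higher and 0 lower genes adjusted over the list alone. Nuclear-retained RNA genes as a list were not called (adjusted p = 0.068 by camera). The nuclear-retained list was called higher without DMSO replicate 1 (adjusted p = 0.018; adjusted p = 0.40 with an estimated correlation). The 47 clustered histone genes were listed at 0 in every library and were not tested. The 13 mitochondrially encoded genes were not analysed here.

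Calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 over 11550 genes. Camera called 10 of the 28 lists tested, 8 higher and 2 lower, and 7 of these without DMSO replicate 1, 6 on the log2(TPM + 1) scale and 8 on log2(TPM + 0.1). The lists called higher include the myeloid markers, whose called genes were near the floor with DMSO. With an estimated correlation DNA replication alone stayed called, and without DMSO replicate 1 heat shock and cholesterol synthesis were called too (adjusted p = 0.025 each). Fry, which does not set a list against other genes, called 18 lists. It called 9 that camera did not (adjusted p = 0.0021 to 0.024), the p53 target, pyroptosis, caspase, FOXO target, NRF2, MYC, doxorubicin and nuclear-retained lists higher and B-cell receptor signalling lower. In 46.8% of genes all erianin libraries lay on one side of all DMSO libraries (2730 above, 2673 below), against 10% by chance. The split between directions depended on the scaling: 49.0% of calls were higher with TMM, 61.7% with upper-quartile scaling, 66.7% with total counts alone and 84.3% on the log2(TPM + 1) scale. Genes changed at least 2-fold were 624 higher and 140 lower with total counts alone, 295 and 34 on log2(TPM + 1), 584 and 60 on log2(TPM + 0.1), and 255 to 655 and 115 to 285 with 1 library left out. The median over genes lay 0.11 above that with TMM for total counts and 0.27 above it for log2(TPM + 1). On the log2(TPM + 1) scale 31 of the 99 named genes called were no longer called, among them CDT1, CDC45, CCNE1, TUBB, RPTOR, MLST8, BCL2 and BCL2L1. The count of changed genes was 777, 745 and 1198 without erianin replicate 1, 2 or 3, and 1794 and 1980 without DMSO replicate 2 or 3. Exons of BCL2L1 (43.0% of bases), PIK3CA (35.8%), TUBA1B (36.6%), TUBB1 (34.0%), MTHFD2 (27.2%) and DDIT3 (27.2%) overlap a gene on the opposite strand, and 36.5% of HSPA1B overlaps a transcript on its own strand, so their counts are uncertain.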

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

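Offsets for GC content and length, sample quality weights and the offsets with DMSO replicate 1 left out were chosen after seeing the data; the other alternatives were planned. With all libraries edgeR called 2791 genes, 1368 higher and 1423 lower, and 688 at least 2-fold. Leaving out 1 library gave 745 to 6505 changed genes, 407 to 3278 higher, 338 to 3227 lower and 370 to 855 at least 2-fold, the lowest without erianin replicate 2 and the highest without DMSO replicate 1; these fits hold fewer samples. Total counts alone left 918 genes lower. On the log2(TPM + 1) scale 1670 genes changed, 262 lower and 329 at least 2-fold, and on log2(TPM + 0.1) 1508 changed and 245 were lower. Offsets for GC content and length gave 2445 lower, quality weights 7408 changed (3699 higher, 3709 lower; weight 0.055 for DMSO replicate 1), and offsets without DMSO replicate 1 gave 7297 (2945 higher, 4352 lower). Testing against 1.5-fold left 294. The rise in calls without DMSO replicate 1 came with a lower common biological coefficient of variation (0.061 against 0.175 with all libraries). Fewer samples do not account for that rise. For the other shifts, apart from fewer samples, the cause was not tested. TPM columns summed to 39.2% of their nominal total in DMSO replicate 1, against 63.6% to 66.7% in the other libraries. A lower sum in 1 DMSO library goes in the direction of the TPM shifts towards higher calls. How much of those shifts it accounts for was not tested. The mitosis median turned to 0.018 on log2(TPM + 0.1), the ATF4 median to 0.015 and 0.016 on log2(TPM + 1) and log2(TPM + 0.1), and CASP4 (-0.17) to 0.25 without DMSO replicate 1 and 0.22 with quality weights, between -0.39 and 0.25 with 1 library left out. Other scalings, filters, DESeq2 and limma-voom kept these counts within 1.5-fold. Of 99 named genes called, 68 were called in all 6 leave-one-out fits, and 31 lost the call on log2(TPM + 1). Whether the numbers pair the libraries could not be decided. Deviations of libraries with the same number correlated at 0.17, -0.14 and 0.23. DMSO replicate 1 correlated at 0.17 with erianin replicate 1 and equally, at 0.17, with erianin replicate 2. Each erianin library correlated with DMSO replicate 1 in one direction and with the other DMSO libraries, almost equally, in the opposite direction. The check therefore could not tell paired from unpaired libraries. With the replicate block 2296 genes were called, 1139 higher and 1157 lower, and 5 named genes lost their call (AKT2, HSP90AB1, ACTB, IGLV1-44 and IGHG3). The planned fit without mitochondrially encoded genes was not run, since no tested gene is one, and DESeq2 gives no list test. The simulation changed 200 of 11550 genes and gave all libraries the same spread per gene. There 13% of 1.5-fold changes were recovered, and 1% with a trend planted in 1 library. The real fit called 2791 genes, and DMSO replicate 1 varied more than the other libraries, so these shares are not its sensitivity.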

Other observations

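Tests of the calls without DMSO replicate 1, of renamed symbols, of a common tubulin fall and of trends as the whole cause, and the symbol families, were chosen only after the result was seen.

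Of 152 families of gene symbols with at least 10 tested members, camera called 3. Genes of the HSPA family of HSP70 chaperones rose, 7 of 12 with none called lower and a median log2 fold change of 0.86 (adjusted p = 2.0e-06; adjusted p = 7.1e-07 without DMSO replicate 1; adjusted p = 0.71 with an estimated correlation). RAD genes, most of them in DNA repair and chromosome cohesion, had 6 of 17 lower, none called higher and a median of -0.32 (adjusted p = 0.0044, 0.063 without DMSO replicate 1 and 0.074 with GC content and length offsets; adjusted p = 0.997 with an estimated correlation). Genes with microRNA-type symbols, many of them host transcripts, had 9 of 36 higher (adjusted p = 0.030, 0.75 without DMSO replicate 1 and 0.68 with the offsets; adjusted p = 0.997 with an estimated correlation).

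DMSO replicate 1 differed by more than 2-fold from the other DMSO libraries in 1241 of 11404 genes, against 214 between those, for example RPLP1 (456 CPM against 2434 and 2910 CPM per total counts). A swap with an erianin library is argued against: over 796 genes its median position was 0.11 on a scale from DMSO (0) to erianin (1). RNA of T, NK, myeloid, epithelial or fibroblast cells is argued against too, since their markers summed to 0.684 times the level in the higher of the other DMSO libraries; other B-lineage cells were not tested and stay open (IGHG3 4439 CPM against 2736 and 2711 CPM, per total counts). Smooth trends in GC content and length explained 28.7% of the variance, with medians of 0.36 in genes of lowest GC content and -0.46 in those of highest. After their removal the SD was 1.83 times that between the other DMSO libraries, which argues against them as the whole cause. A part through such trends may remain open, as does a difference in the culture, which was not tested. Erianin replicate 3 carried a weaker GC trend of the opposite sign against erianin replicates 1 and 2. There the trends explained 25.6% of the variance, with medians of -0.17 in genes of lowest GC content and 0.17 in those of highest. They explained 0.37% between DMSO replicates 2 and 3 and 0.49% between erianin replicates 1 and 2. With DMSO replicate 1 left out 6505 genes were called, but its wider spread made a rise in number likely in advance. Of the 2791 genes called with all libraries, 2784 were called in the same direction without it. This argues against DMSO replicate 1 alone as the source of the calls.

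The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 2791 edgeR calls, and 1 of 10 splits, itself, gave as many. The highest of the others gave 0, with 25 to 1224 genes at an unadjusted p under 0.05. Each of those splits mixed erianin and DMSO libraries in both groups, so treatment differences widened the spread within them. Their lack of calls therefore gives no null level for the real split. All 10 lists that camera called kept direction and call with GC content and length offsets, which argues against those trends as their source.

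Tubulin mRNA is known to fall when free tubulin dimers accumulate, as with compounds that block polymerisation. A common fall of alpha- and beta-tubulin mRNAs was not seen after 24 h: 3 of these genes rose and 1, TUBB, fell. Of the 3, TUBB1 was at a low level, and 34.0% of its exonic bases overlap a gene on the opposite strand. Without DMSO replicate 1, TUBA1B was called lower and TUBB4B higher. Changes of single tubulin genes may have other sources, which these data do not separate. Histone and other genes listed at 0 in every library are a separate matter: 91.01% of renamed protein-coding genes were at 0, which is consistent with symbols renamed after the annotation used for counting.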
